A study of Homo sapiens with 32 samples.

How the data were processed

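RNA sequencing was done on 32 libraries of 2 cell lines, Kasumi-1 and SKNO-1, at 2 times with 4 agents and 2 biological replicates per group. Per the labels, Kasumi-1 grew in RPMI with 20% fetal calf serum and SKNO-1 in RPMI with 10% serum and 10 ng/mL GM-CSF, and cells were given 0.1% DMSO or a compound at 1 µM. RNA was extracted with Trizol or RNeasy Plus. The authors deposited a table of FPKM per gene and library, a table that gives each Ensembl gene its gene symbols and its locus (chromosome, start and end), and a table of replicate titles. The authors' notes name TopHat 1.4.1, Cufflinks and the hg19 genome, with no order or role for each. The annotation release, the library type and any further scaling of the FPKM values are not stated. The replicate titles in the authors' table give the opposite cell line for all 16 libraries at 72 h, and the titles in the labels were used.

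The deposited FPKM table holds 23073 genes. In it 5077 genes stand at 0 in every library, and 30 genes have no value in some libraries (102 cells), which were treated as missing. The 2532 genes placed off the primary chromosomes did not pass the filter, and neither did the mitochondrial genes, which stand at 0 in every library, so the share of mitochondrial RNA cannot be read. Read counts were not used here, so the depth per library is unknown and no interval for counting error was computed. Relative depth, read from genes whose FPKM was at most 0.2 and present in 4 to 12 libraries, was 0.759 to 1.39, from 1 to 32 genes per library (median 16), which is too few for more than a rough guide.

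Genes with at least 1 FPKM in at least 2 libraries were kept (11890). Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 16 groups and a trend of the variance on the mean (16 residual and 5.23 prior degrees of freedom). The contrasts in each set of cell line and time were RN-1 against DMSO, GSK690 against GSK690*, GSK690* against DMSO, RN-1 against GSK690, and the mean of both inhibitors against the mean of both controls. Differences of the last contrast between 72 and 24 h in each line, and between the lines at each time, were tested as interaction terms. All tests were 2-sided, and p was adjusted by Benjamini and Hochberg over the tested genes of each contrast, with a threshold of 0.05. Tables were prepared and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

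The samples, contrasts, other ways of fitting, the rule for named genes and 27 gene lists were set before the data were examined. The lists cover the KDM1A complex, flavin amine oxidases, histone demethylases, monocytes and macrophages, neutrophils, mast cells, basophils and eosinophils, erythroid cells, megakaryocytes, stem and progenitor cells, myeloid transcription factors, genes high in t(8;21) leukaemia, class II and class I antigen presentation, interferon response, cytokines and NF-kB response, proliferation, MYC and ribosome biogenesis, p53 and BCL2 family, cyclin-dependent kinase inhibitors, cholesterol synthesis, lysosome and phagocytosis, stress and hypoxia, mitochondrial RNA, replication-dependent histones, T and NK cells, B cells, and adherent cells. Some genes are in more than 1 list, such as CTSS and GATA2. The 22 lists with at least 5 tested genes in every comparison were tested with camera (correlation preset to 0.01), again with camera's estimated correlation, and with fry, and p was adjusted over the 22. For the other 5, counts alone are given. Each list also has a count of genes with p adjusted over the list alone.

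Genes were named by rule. In each set, the rule takes the 8 highest and 6 lowest log2 changes with the inhibitors among genes that passed and whose 4 inhibitor libraries all lay above or all below the 4 controls, and up to 3 members of each list with the largest change among those that passed. It adds up to 4 genes from GSK690* against DMSO, RN-1 against GSK690 and each interaction. KDM1A, RCOR1, GFI1, GFI1B, SPI1, CEBPA, ITGAM and CD86 were followed whatever their values, and genes without a symbol were passed over. The values of 3 named genes are not reported here. Of these, the ones given for the 4 sets were chosen among genes that kept their call in each fit without 1 library, so they are steadier than the called genes at large.

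The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, scaling by the median of ratios, a fit on the 8 libraries of a set alone, a fit of those 8 as 2 groups of 4, a block for replicate number, a term for the prefix of the library names in SKNO-1 at 72 h, each library left out in turn, and the other list tests. After the data were seen, a fit without GSK690* among the controls and a mean of the contrasts over the 4 sets were added. The fit was tested on simulated data of 11862 genes drawn around the mean of each set with each gene's moderated variance from the fit. With 4 against 4 libraries it called 66% to 88% of genes given a change of log2 0.5 in the 4 sets, and 100% of those given 1. Over all contrasts, those of 2 against 2 libraries included, there were 4 to 14 false calls beside 169 to 205 calls in all, and 0 calls without any effect. The simulated libraries varied independently, with 1 variance per gene. These rates therefore do not cover replicates that vary together (r up to 0.697 between deviations of same-numbered libraries) or sets of unequal spread. Groups of libraries were also split in other ways, with 35 splits of each set and 100 seeded regroupings for each interaction. No file was left out. The replicates are numbered without a shared batch in the labels, so replicate number is not a term of the fit.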

Results

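RNA was measured by sequencing in 32 cultures of 2 human acute myeloid leukaemia cell lines, Kasumi-1 and SKNO-1, both of which carry the RUNX1-RUNX1T1 fusion. Each line was given the vehicle DMSO, RN-1, GSK690 or GSK690* for 24 or 72 h. Per the labels, each of the 16 groups has 2 biological replicates. RN-1 inhibits the histone demethylase KDM1A irreversibly, GSK690 inhibits it reversibly, and GSK690* is an isomer of GSK690 that the labels call inactive. For SKNO-1, the titles of the later libraries give 72 h and the treatment protocol gives 4 days. The authors' own sample table names the opposite cell line for the 16 libraries at 72 h, and the titles in the labels were used here. By those titles, each 72 h library had a mean Pearson r across genes of 0.974 to 0.986 with the 24 h libraries of its own line and of 0.848 to 0.870 with those of the other line.

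Read counts were not used here, so the depth of each library is unknown. FPKM summed over genes ran from 332648 to 395945 per library (median 366560), and 10551 to 10970 genes reached 1 FPKM. The 2 replicates of a group correlated across genes with a Pearson r of 0.986 to 0.996 (median 0.994). The 10 most abundant genes took 4.39% to 8.0% of the FPKM of a library at 24 h and 2.79% to 3.9% at 72 h. In all, 11890 of 23073 genes passed the filter on low values. FPKM values in the comparisons of inhibitors with controls are means ± SD over 4 libraries per side, and log2 changes are on the scale of log2(FPKM + 1) with their SE. On this scale the fold change of a gene near 0 FPKM is understated. A gene is said to have risen or fallen only with a limma adjusted p under 0.05. Where counts at an unadjusted p under 0.05 are given, chance alone would bring about 0.05 of the genes tested there.

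The target itself and the transcription factors that recruit it were followed in every comparison. KDM1A (chromosome 1, 23345940 to 23410182, hg19) has no deposited value in 15 of the 32 libraries. In SKNO-1 it stood at 69.4 ± 0.970 FPKM in 2 control and 63.2 ± 1.91 FPKM in 2 inhibitor libraries at 24 h. At 72 h it stood at 82.6 ± 2.37 and 75.6 ± 4.51 FPKM in 3 libraries each. The log2 changes of -0.13 and -0.16 did not pass (adjusted p = 0.436 and 0.245). In Kasumi-1 no DMSO library has a value, so the contrast of both inhibitors with both controls could not be fitted at either time. KDM1A stood there at 69.7 FPKM in 1 control and 62.7 ± 3.02 FPKM in 3 inhibitor libraries at 24 h. At 72 h it stood at 75.1 FPKM in 1 and 69.8 ± 2.09 FPKM in 2. In each of the 4 sets the inhibitor values present lay below the control values present. RCOR1, a scaffold of the complex that KDM1A works in, and the myeloid regulators SPI1 and CEBPA passed in no set of cell line and time. SPI1 changed by log2 0.16, -0.04, 0.06 and -0.14 in Kasumi-1 at 24 and 72 h and SKNO-1 at 24 and 72 h.

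GFI1, a repressor that brings KDM1A to its target genes, rose in all 4 sets, by log2 0.53 ± 0.066, 0.63, 0.45 and 0.50 in the same order. In Kasumi-1 at 24 h it went from 125 ± 9.58 to 181 ± 7.58 FPKM. Its paralog GFI1B (chromosome 9, 135820931 to 135867083) was close to 0 FPKM in controls of both lines. In SKNO-1 it rose by log2 2.59 ± 0.45 at 24 h and by 3.82 at 72 h, when it went from 0.0917 ± 0.108 to 14.9 ± 5.11 FPKM. In Kasumi-1 it stayed at 0.203 ± 0.137 FPKM or less with the inhibitors and did not pass. The difference between the lines passed at 72 h (log2 -3.59, adjusted p = 0.00139) and not at 24 h (adjusted p = 0.0568). ITGAM, which codes for the integrin chain CD11b of mature myeloid cells, rose by log2 0.81 and 1.48 in Kasumi-1 and by 0.86 and 1.54 in SKNO-1. Its call in SKNO-1 at 24 h ended without GSK690 replicate 1, GSK690* replicate 2 or RN-1 replicate 1 (adjusted p = 0.0580 to 0.136). CD86 (chromosome 3, 121774212 to 121839983), a T cell costimulatory ligand, rose in all 4 sets, by log2 2.25, 1.64 and 1.73 in the first 3 of them (SE 0.094).

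**Figure D1:**
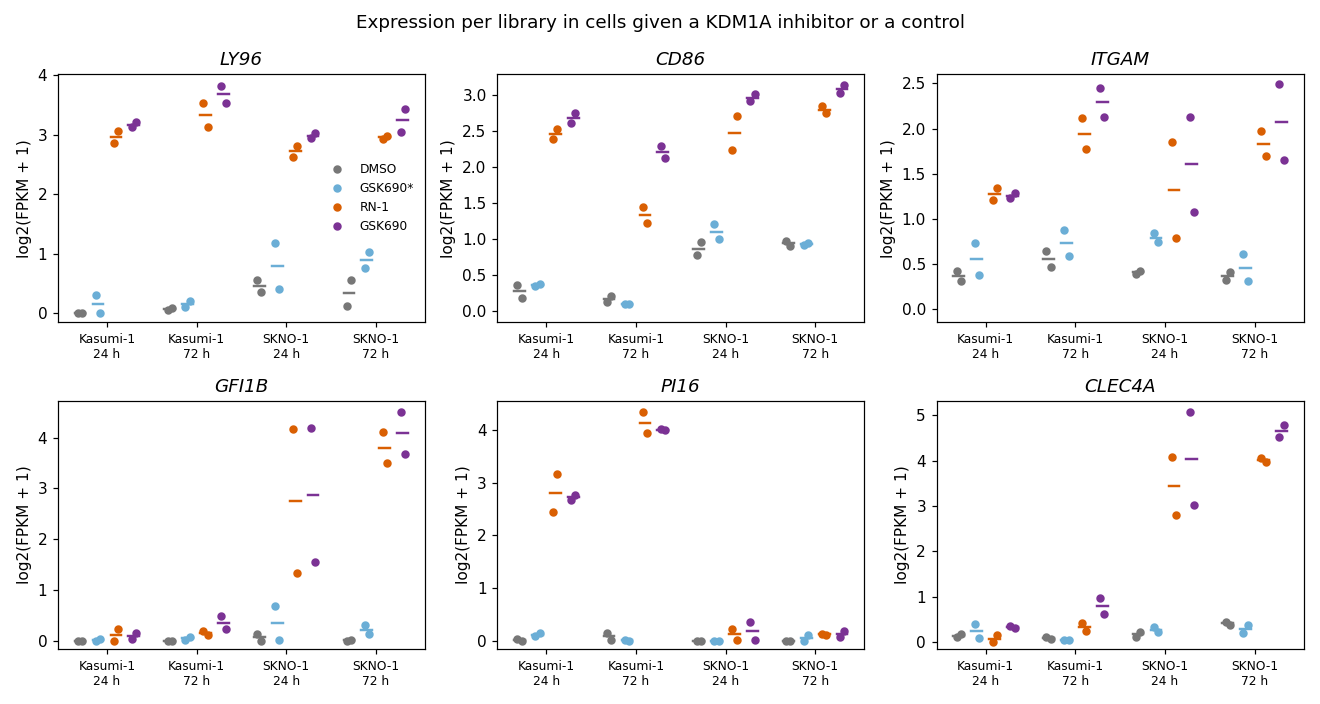
Expression as log2(FPKM + 1) of 6 genes in each of the 32 libraries by cell line and time, with a point per library and a line at the mean of the 2 replicates of a group, coloured by agent. LY96, CD86 and ITGAM rose in both lines, GFI1B and CLEC4A rose in SKNO-1, and PI16 rose in Kasumi-1.

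The comparison of the 4 RN-1 and GSK690 libraries with the 4 DMSO and GSK690* libraries asks which genes respond to inhibition of KDM1A. In Kasumi-1 at 24 h most changes were small. Of 11887 genes tested, 1152 rose and 1327 fell, and 77 rose and 1 fell by at least 2-fold. LYZ (chromosome 12, 69742120 to 69748014), the lysozyme of monocytes and granulocytes, went from 15.4 ± 8.40 to 122 ± 25.7 FPKM, log2 3.01 ± 0.17 (adjusted p = 6.43e-11). LY96 (chromosome 8, 74903586 to 74941322), with which TLR4 binds lipopolysaccharide, rose from 0.0585 ± 0.117 to 7.44 ± 0.852 FPKM (adjusted p = 2.08e-12). KCTD12, a subunit of GABA-B receptors, rose by log2 2.74, and PI16, a secreted protease inhibitor, rose by log2 2.69 to 5.88 ± 1.49 FPKM. MS4A4A, a surface protein of macrophages, rose by log2 2.54. The protease inhibitor SERPINB8 and GLIPR1 rose by log2 2.22 and 2.19. MT2A, a metallothionein that binds zinc and copper, fell from 65.3 ± 13.2 to 29.6 ± 3.92 FPKM, log2 -1.11 ± 0.21 (adjusted p = 7.51e-04). CD180, a Toll-like receptor homologue, fell by 0.97. TFRC, the transferrin receptor, decreased by 0.59, and BOLA3, a mitochondrial iron-sulfur cluster factor, by 0.71.

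Both sides of this comparison were separated in 3872 genes (32.6%), where chance gives 2.86%. The count of 2479 genes depended on single libraries. It was 1501 without DMSO replicate 1, 1498 without GSK690 replicate 2, 1504 without GSK690* replicate 1 and 1546 without RN-1 replicate 2. A scaling by the median of ratios moved the balance from 46.5% to 58.4% of called genes rising, with 1428 higher and 1018 lower. Neither this scaling nor quantile normalization reversed the direction of any list.

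Of 22 gene lists fixed before the data were examined, 12 were called in Kasumi-1 at 24 h by camera, 9 up and 3 down. Among 20 tested markers of monocytes and macrophages, 10 rose, 1 fell and 9 did not pass, and with p adjusted over the list alone 13 rose and 1 fell (median log2 0.38, camera adjusted p = 3.25e-11). CTSS, a lysosomal protease that trims the class II chaperone, rose by log2 1.37. This was the single list that held with an estimated correlation (adjusted p = 0.0033), and the other 11 were lost, with adjusted p = 0.0947 to 0.399. The proliferation genes moved almost as a block: 34 of 36 fell and 2 did not pass, 35 adjusted over the list alone (median -0.44, camera adjusted p = 3.09e-21, and adjusted p = 0.112 with an estimated correlation). The replication factor MCM10 and the replisome component GINS2 fell by 0.67 and 0.65, and cyclin A2 (CCNA2) by 0.61. Among MYC and ribosome biogenesis genes 16 of 25 fell, 16 adjusted over the list alone, and among genes of cholesterol synthesis 6 of 20 fell, 11 adjusted over the list alone (SQLE, log2 -0.57).

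In the class I presentation list of Kasumi-1 at 24 h 5 of 15 genes rose, 10 adjusted over the list alone (median 0.35, camera adjusted p = 6.98e-05, and adjusted p = 0.355 with an estimated correlation). They include the immunoproteasome subunit PSMB9 (log2 0.81) and the peptide trimmer ERAP2 (0.65). In the class II list 1 of 10 rose in either count. Of 13 cytokine, chemokine and NF-kB response genes 5 rose, 7 up and 1 down adjusted over the list alone, with IL8 at log2 1.46 and NFKBIA at 0.60. Of 8 B and plasma cell markers 3 rose, 4 adjusted over the list alone. Of 35 interferon-stimulated genes 5 rose in either count, with TRIM22 at 1.21 and HERC5 at 1.18. That list was lost without GSK690 replicate 2 or RN-1 replicate 2 (adjusted p = 0.152 to 0.175). The lysosome list (7 of 20 rose in either count, CTSB at 0.48) was lost without DMSO replicate 2 (adjusted p = 0.0906). The list of myeloid transcription factors (4 of 18 rose in either count) was lost without GSK690* replicate 1 (0.0572). The replication-dependent histones (3 of 8 rose, 4 adjusted over the list alone) were lost without DMSO replicate 2, GSK690 replicate 2, GSK690* replicate 1 or RN-1 replicate 2 (0.0529 to 0.0956). Quantile normalization ended the calls of the class II, histone and B cell lists and added the histone demethylases, and the median of ratios ended those of class II and histones. Leaving out RN-1 replicate 1 added the histone demethylases (0.0425), and leaving out RN-1 replicate 1 or GSK690* replicate 2 added the stem and progenitor list (0.0440 to 0.0492).

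In Kasumi-1 at 72 h the monocyte and macrophage list was again called up. Of 11887 genes tested, 1547 rose and 1505 fell, and 173 rose and 13 fell by at least 2-fold. The balance moved with the fit, to 1759 up and 1262 down with the median of ratios, 1530 and 1650 with quantile normalization and 1414 and 1010 in a fit on these 8 libraries. PI16 (chromosome 6, 36922208 to 36932613) had the highest change, log2 4.02 ± 0.12, from 0.0368 ± 0.0526 to 15.9 ± 2.24 FPKM (adjusted p = 2.52e-16). KCTD12 (chromosome 13, 77454311 to 77460540) rose by log2 3.85 from 1.26 ± 0.225 to 31.7 ± 4.57 FPKM. LY96 rose by 3.40 to 10.6 ± 2.24 FPKM and LYZ by 2.48 to 67.8 ± 10.4 FPKM. RGMB, a co-receptor for bone morphogenetic proteins, rose by log2 2.76, GLIPR1 by 2.55 and MS4A4A by 2.44. GPR84, a receptor for medium-chain fatty acids on myeloid cells, rose by 2.46. CD34, the stem and progenitor surface marker, rose by log2 1.41 from 83.9 ± 15.5 to 223 ± 24.2 FPKM, while KIT, the stem cell factor receptor, fell by 0.52 from 304 ± 11.9 to 213 ± 25.7 FPKM. CD180 fell by 1.47 and MT2A by 1.28. MYC fell by 0.48 from 180 to 129 FPKM, and the ribosome assembly factor RRP12 by 0.56. CDKN1B, the cyclin-dependent kinase inhibitor p27, rose by 0.47. The 4 inhibitor and 4 control libraries did not overlap in 3405 genes (28.6%), where chance gives 2.86%. The count of 3052 genes was 2022 without DMSO replicate 1.

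Camera called 13 of the 22 lists in Kasumi-1 at 72 h, 10 up and 3 down. Monocyte and macrophage markers had 12 of 20 genes up and 8 not passing, 12 up and 1 down adjusted over the list alone (median 0.68, camera adjusted p = 3.01e-09). They again held with an estimated correlation (adjusted p = 0.00743), and the other 12 lists were lost, with adjusted p = 0.196 to 0.550. In the class I list 12 of 15 genes rose, 13 adjusted over the list alone (median 0.55, camera adjusted p = 8.22e-08, and adjusted p = 0.196 with an estimated correlation). PSMB9 rose by log2 1.45 and HLA-C by 1.12, where reads shared among HLA genes leave each HLA value uncertain. In the class II list 2 of 10 rose in either count, CTSS (1.35) and the lysosomal thiol reductase IFI30 (1.55). Of the cytokine and NF-kB genes 7 rose and 1 fell of 13, 10 and 1 adjusted over the list alone. NFKBIZ rose by 1.15, while the chemokine CCL5 fell by 0.83. Interferon-stimulated genes had 7 of 35 up, 6 adjusted over the list alone, with TRIM22 at 1.43 and HERC5 at 1.13. Genes of cholesterol synthesis had 14 of 20 down, 15 adjusted over the list alone (median -0.53, camera adjusted p = 4.06e-07, and adjusted p = 0.402 with an estimated correlation), with DHCR7 at log2 -0.84. Proliferation genes had 21 of 36 down, 24 adjusted over the list alone, with MCM4 at -0.55 and MCM2 at -0.46, and MYC and ribosome genes had 12 of 25 down, 18 adjusted over the list alone.

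Smaller lists followed in Kasumi-1 at 72 h. Stem and progenitor genes had 8 of 19 up and 1 down in either count, among them ERG (log2 0.71), a transcription factor of stem cells, and SPINK2 (0.73). Replication-dependent histones had 4 of 8 up in either count, with HIST1H2AC at 1.27, HIST2H2BE at 0.93 and HIST1H2BD at 0.88. Lysosomal genes had 6 of 20 up in either count, with CTSB at 0.72 and the cholesterol carrier NPC2 at 0.67. B and plasma cell markers had 4 of 8 up, 5 up and 1 down adjusted over the list alone, and were lost without RN-1 replicate 1 (adjusted p = 0.0619). Myeloid transcription factors had 6 of 18 up and 1 down in either count, with NFE2 at 0.48. They were lost without DMSO replicate 1, GSK690* replicate 1 or RN-1 replicate 1 (0.0536 to 0.109). Quantile normalization also ended the calls of the B cell and transcription factor lists.

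Of 11888 genes tested in SKNO-1 at 24 h, 671 rose and 409 fell, and 86 rose and 1 fell by at least 2-fold. FCGR2B, the inhibitory IgG receptor, rose by log2 3.55 ± 0.24 from 0.873 ± 0.279 to 23.6 ± 13.8 FPKM (adjusted p = 1.98e-09). FCGR2C rose by log2 2.67, but the sequences of the pair are nearly alike, so reads may be counted under either. CLEC4A, an inhibitory lectin of dendritic cells and monocytes, rose by log2 3.52 ± 0.28 from 0.169 ± 0.0723 to 15.4 ± 12.3 FPKM (adjusted p = 1.65e-08). TSPAN7, a membrane tetraspanin, rose by 2.81, and GZMA, a granzyme of cytotoxic lymphocytes, by 2.80. The membrane-binding protein ANXA2 rose by log2 2.64 and the secreted inhibitor WFDC1 by 2.48. AGTRAP, which internalizes the angiotensin receptor, fell by 0.65, the potassium channel KCNH2 by 1.04 and the prostaglandin receptor PTGER2 by 0.79. The 4 inhibitor and 4 control libraries did not overlap in 1801 genes (15.1%), where chance gives 2.86%.

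The count of 1080 genes in SKNO-1 at 24 h rested on single libraries more than in the other sets. It was 551 without DMSO replicate 1, 571 without DMSO replicate 2, 387 without GSK690 replicate 1, 494 without GSK690* replicate 2 and 405 without RN-1 replicate 1. It was 160 in a fit on these 8 libraries alone and 491 with 2 groups of 4, and it was 668 with GSK690* left out of the controls, an alternative added after the data were seen. In the fit on 8 libraries KCNH2, PTGER2, GFI1B and GFI1 no longer passed. The share of called genes rising went from 62.1% to 60.6% with quantile normalization, to 75.2% with the median of ratios, 829 up and 273 down, to 73.5% with GSK690* left out of the controls and to 88.8% in the fit on 8 libraries, 142 up and 18 down.

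Camera called 12 of the 22 lists in SKNO-1 at 24 h, 9 up and 3 down, and 2 held with an estimated correlation. Those were monocyte and macrophage markers, with 9 of 20 up and 1 down, 11 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 4.47e-08, estimated 0.0139), and the cytokine and NF-kB genes. The latter had 6 of 13 up, 8 adjusted over the list alone (median 0.49, camera adjusted p = 1.45e-04, estimated 0.0372), with the interleukin IL1B at log2 0.99. The other 10 were lost, with adjusted p = 0.0900 to 0.633. LY96 rose by 2.23, CD86 by 1.73 and CTSS by 0.52. Mast cell, basophil and eosinophil markers had 6 of 13 up and 1 down, 8 and 1 adjusted over the list alone (median 0.72, camera adjusted p = 0.00865, and adjusted p = 0.0900 with an estimated correlation). ALOX5, which starts leukotriene synthesis, rose by 1.53, and FCER1A, a chain of the IgE receptor, by 1.45. That list was lost without DMSO replicate 1 (adjusted p = 0.0811), in the fit on 8 libraries (0.0657) and with 2 groups of 4 (0.0571). Replication-dependent histones had 5 of 8 up, 6 adjusted over the list alone (median 0.76, camera adjusted p = 2.20e-05, and adjusted p = 0.246 with an estimated correlation). Class I presentation had 4 of 15 up, 7 adjusted over the list alone, and class II had 1 of 10 up in either count.

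Proliferation genes in SKNO-1 at 24 h had 7 of 36 down, 12 adjusted over the list alone (median -0.18, camera adjusted p = 2.61e-06, and adjusted p = 0.368 with an estimated correlation). MYC and ribosome genes had 1 of 25 down in either count, and cholesterol synthesis had 3 of 20 down, 8 adjusted over the list alone (median -0.34, camera adjusted p = 1.53e-05, and adjusted p = 0.376 with an estimated correlation). Interferon-stimulated genes had 2 of 35 up in either count. They were lost without GSK690 replicate 1, GSK690* replicate 1 or RN-1 replicate 2 (adjusted p = 0.0557 to 0.0971) and with either other scaling. Lysosomal genes had 5 of 20 up, 7 up and 1 down adjusted over the list alone, and were lost without DMSO replicate 2, GSK690* replicate 2 or RN-1 replicate 1 (0.0660 to 0.0869). Myeloid transcription factors had 4 of 18 up in either count, with the inhibitory factor ID2 at log2 0.85, and were lost without RN-1 replicate 1 (0.0628). B cell markers were added without DMSO replicate 2, GSK690 replicate 1, GSK690* replicate 2 or RN-1 replicate 1 (0.00534 to 0.0171), and neutrophil genes, falling, without GSK690 or RN-1 replicate 2 (0.00581 to 0.0372). The p53 list was added without GSK690 replicate 2 (0.0292), and the list of genes high in t(8;21) leukaemia without DMSO replicate 2 (0.0449).

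Of 11889 genes tested in SKNO-1 at 72 h, 1316 passed and 495 of them fell, and 122 rose and 2 fell by at least 2-fold. CLEC4A rose by log2 3.98 ± 0.28 from 0.281 ± 0.0922 to 19.8 ± 5.68 FPKM (adjusted p = 1.71e-09), and FCGR2B rose to 29.4 FPKM. GZMA rose by 3.38 ± 0.13 from 0.145 ± 0.0964 to 11.1 ± 2.46 FPKM (adjusted p = 2.69e-13). TSPAN7 rose by 3.27, ANXA2 by 2.84 and WFDC1 by 2.63. CD34 rose by log2 1.53 from 0.477 ± 0.189 to 3.41 ± 1.37 FPKM, and GATA2, a factor of progenitors and mast cells, by 0.86. MFAP4 and KCNH2 fell by 1.19 and 1.18. The eosinophil protein CLC fell by 0.97 from 12.8 ± 2.67 to 5.99 ± 0.857 FPKM, and SNTB1 by 0.93. TNFRSF10B, a receptor for the death ligand TRAIL, rose by log2 1.78, and TP53I3 by 0.76. The 4 inhibitor and 4 control libraries did not overlap in 1810 genes (15.2%), where chance gives 2.86%. The count of 1316 genes was 860 without DMSO replicate 1 and 871 without GSK690* replicate 1, 400 in a fit on these 8 libraries alone (349 up and 51 down) and 799 with 2 groups of 4 (592 up and 207 down). In this set 6 of the 8 libraries have names with another prefix than the rest, and with a term for the prefix the count was 1610, 930 up and 680 down.

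Camera called 12 of the 22 lists in SKNO-1 at 72 h, 9 up and 3 down, and 3 held with an estimated correlation. Monocyte and macrophage markers had 10 of 20 up and 2 down, 12 and 3 adjusted over the list alone (median 0.49, camera adjusted p = 1.11e-07, estimated 0.0173). Mast cell, basophil and eosinophil markers had 8 of 13 up and 2 down, 8 and 3 adjusted over the list alone (median 0.86, camera adjusted p = 0.00146, estimated 0.0274), with ALOX5 at 1.88 and FCER1A at 1.72. The cytokine and NF-kB genes had 7 of 13 up, 7 up and 1 down adjusted over the list alone (median 0.45, camera adjusted p = 6.63e-05, estimated 0.0225), with TNF at 1.44, IL1B at 1.20 and the adhesion molecule ICAM1 at 1.07. The other 9 were lost, with adjusted p = 0.148 to 0.594. Class I presentation had 5 of 15 up, 9 adjusted over the list alone (camera adjusted p = 2.52e-04, and adjusted p = 0.303 with an estimated correlation). Class II had 2 of 10 up, 5 adjusted over the list alone (median 0.65, camera adjusted p = 1.23e-04, estimated 0.303). Replication-dependent histones had 5 of 8 up in either count (HIST1H2BD at 1.03), and interferon-stimulated genes had 2 of 35 up in either count. Cholesterol synthesis had 4 of 20 down, 9 adjusted over the list alone (median -0.35, camera adjusted p = 6.55e-05, estimated 0.465), and MYC and ribosome genes had 2 of 24 down in either count.

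Several list calls in SKNO-1 at 72 h rested on single libraries. Proliferation genes (1 of 36 down in either count, median -0.09, camera adjusted p = 0.0323, and adjusted p = 0.594 with an estimated correlation) were lost without DMSO replicate 1, GSK690 replicate 2, GSK690* replicate 1 or RN-1 replicate 2 (adjusted p = 0.347 to 0.667). Myeloid transcription factors (4 of 18 up and 1 down, 5 and 2 adjusted over the list alone) were lost without DMSO replicate 1, GSK690 replicate 1, GSK690* replicate 2 or RN-1 replicate 2 (0.145 to 0.178). Genes high in t(8;21) leukaemia (3 of 14 up, 4 adjusted over the list alone) were lost without the same 4 libraries (0.0524 to 0.103). Quantile normalization ended these 3 calls and added the lysosomal genes, and the median of ratios ended that of the transcription factors. Lysosomal genes were also added without GSK690* replicate 1 or RN-1 replicate 2 (0.0235 to 0.0296) and megakaryocyte markers without RN-1 replicate 1 (0.0211). Falling neutrophil genes were added without DMSO replicate 1, GSK690 replicate 2 or RN-1 replicate 2 (0.0192 to 0.0446), and stem cell genes without GSK690* replicate 2 (0.0495).

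Of the lists not called, neutrophil granule genes had 2 up and 1 down of 14 in Kasumi-1 at 24 h, 1 and 5 at 72 h (1 and 6 adjusted over the list alone), and 0 at either time in SKNO-1 by limma. The neutrophil list was called down in Kasumi-1 at 72 h in the fit on 8 libraries (adjusted p = 0.0128) and with 2 groups of 4 (0.0266). Mast cell, basophil and eosinophil markers had 1 up and 1 down of 13 in Kasumi-1 at 24 h and 2 up and 1 down at 72 h. At 24 and 72 h that list was called up in the fit on 8 libraries (0.0265 and 0.0119), with 2 groups of 4 (0.0334 and 0.0124) and with a pseudocount of 0.1 (0.0428 and 0.0164), and by fry at 72 h alone (0.0297). The KDM1A complex and its GFI factors had 2 up and 2 down of 12 (3 and 2 adjusted over the list alone), 2 up of 12, and in SKNO-1 3 up and 1 down of 13 at both times. Among the histone demethylases JHDM1D rose in Kasumi-1, by log2 0.81 and 0.46, and 0 of 17 passed in SKNO-1 by limma. Stress and hypoxia genes in Kasumi-1 at 24 h divided, 5 up and 5 down of 23 (6 and 5 adjusted over the list alone). The stress regulators DDIT4 (1.07) and NDRG1 (0.60) rose, and the 5 that fell were heat shock genes, read after their values were seen. At 72 h 6 rose and 1 fell, and in SKNO-1 2 rose at 24 h (3 up and 3 down adjusted over the list alone), and 2 rose and 1 fell at 72 h. Of 21 p53 targets and BCL2-family genes 3 to 4 rose in each set, TNFRSF10B among them in all 4, and 2, 3, 0 and 1 fell. Of 6 cyclin-dependent kinase inhibitors 1 and 2 rose in Kasumi-1 (3 up and 1 down at 72 h adjusted over the list alone) and 0 in SKNO-1. Of 6 megakaryocyte markers 0, 1, 0 and 2 rose. The median was below 0 where the test pointed up for neutrophil and p53 genes in Kasumi-1 at 24 h, for the KDM1A complex at 72 h in both lines, and for stress genes in Kasumi-1 at 72 h and SKNO-1 at 24 h. Of the lists with fewer than 5 tested genes in some comparison, T and NK cell markers had 1, 3, 1 and 2 of 4 up, GZMA in every set. Flavin amine oxidases had 1, 2, 1 and 1 up of 4 or 5. Of 5 erythroid genes 1 fell in Kasumi-1 at 24 h and 0 passed in the other sets. The 1 tested gene of adherent cells did not pass, and no mitochondrial transcript could be tested, as all stand at 0.

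**Figure D2:**
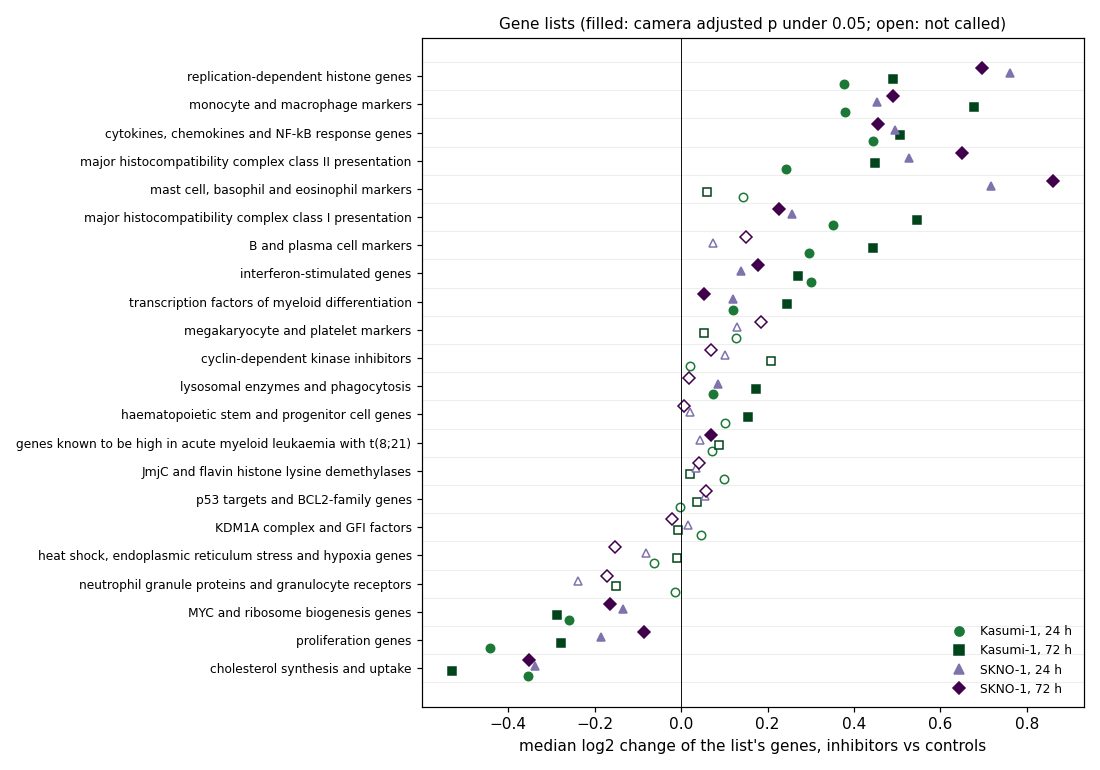
Median log2 change of the tested genes of 22 gene lists, 4 inhibitor against 4 control libraries, by cell line and time, with filled symbols for a camera adjusted p under 0.05. Monocyte and macrophage markers were called up in all 4 sets. Cholesterol synthesis genes were called down in all 4, and none of these calls held with an estimated correlation (adjusted p = 0.376 to 0.465).

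Across the 4 sets, 313 genes rose in all and 91 fell in all. LY96 was raised by at least log2 2.23 in each, and KCTD12 by at least 1.70. ERG rose by log2 0.57 to 0.71 and TNFRSF10B by 1.20 to 1.78. In Kasumi-1, 940 genes rose and 781 fell at both times, where independent lists of these sizes would share 150 and 168. In SKNO-1, 539 rose and 207 fell at both times, against 46.3 and 17.0 by chance. At 72 h, 492 rose and 261 fell in both lines, against 107 and 62.7. At 24 h, 383 rose and 221 fell in both lines, against 65.0 and 45.7.

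Each compound was also set against its own control, 2 libraries against 2, to ask whether an irreversible and a reversible inhibitor change the same genes. Both raised LY96, by log2 2.97 with RN-1 and 3.02 with GSK690 in Kasumi-1 at 24 h. Both raised PI16 in Kasumi-1 at 72 h, by 4.04 and 3.99, and GFI1B in SKNO-1 at 72 h, by 3.78 and 3.86. Against DMSO, RN-1 raised 650 and lowered 429 genes in Kasumi-1 at 24 h and raised 885 and lowered 548 at 72 h. In SKNO-1 it raised 216 and lowered 51 at 24 h and raised 349 and lowered 63 at 72 h. Against GSK690*, GSK690 raised 299 and lowered 169 genes and then raised 716 and lowered 443 in Kasumi-1. In SKNO-1 it raised 181 and lowered 13 and then raised 301 and lowered 36. Of the genes raised by GSK690, 265, 574, 141 and 235 in Kasumi-1 at 24 and 72 h and SKNO-1 at 24 and 72 h were also raised by RN-1, which is 88.6%, 80.2%, 77.9% and 78.1% of the smaller list. Chance would give 16.3, 53.3, 3.29 and 8.84. Of the genes lowered, 121, 196, 5 and 20 were shared, 71.6%, 44.2%, 38.5% and 55.6% of the smaller list, where chance would give 6.10, 20.4, 0.0558 and 0.191.

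Nearly all of these counts moved by more than 1.5-fold when a library was left out. For RN-1 in Kasumi-1 at 24 h, the 1079 genes became 273 and 510 without DMSO replicate 1 and 2 and 496 and 335 without RN-1 replicate 1 and 2. At 72 h, the 1433 became 587 without DMSO replicate 1 and 694 without RN-1 replicate 1. In SKNO-1 at 24 h, the 267 became 98 and 106 without DMSO replicate 1 and 2, 87 without RN-1 replicate 1 and 536 without RN-1 replicate 2. At 72 h, the 412 became 201 without DMSO replicate 1 and 236 and 211 without RN-1 replicate 1 and 2. For GSK690 in Kasumi-1 at 24 h, the 468 became 209 and 130 without GSK690 replicate 1 and 2 and 147 and 299 without GSK690* replicate 1 and 2. At 72 h, the 1159 became 593 and 426, and 391 and 587, in the same order. In SKNO-1 at 24 h, the 194 became 64 and 438 without GSK690 replicate 1 and 2 and 63 without GSK690* replicate 2. At 72 h, the 337 became 199 and 183 without GSK690 replicate 1 and 2 and 155 without GSK690* replicate 1.

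The effects of the compounds were also compared across all tested genes, with no library in common between the 2 contrasts. RN-1 against DMSO and GSK690 against GSK690* correlated with a Pearson r of 0.814 and 0.829 in Kasumi-1 at 24 and 72 h and of 0.810 and 0.852 in SKNO-1 (Spearman rho 0.741, 0.730, 0.699 and 0.733). These are correlations across genes within a set, and genes are not independent replicates, so no p is given. Over genes called at the other time of the same line, r was 0.931, 0.949, 0.952 and 0.965, and the slope of GSK690 on RN-1 was 0.796, 0.924, 0.898 and 0.928. These slopes do not show that GSK690 is weaker, since the controls differ and noise in the RN-1 values lowers a slope. On genes raised at least 2-fold at the other time, GSK690* itself lay above DMSO, by a median log2 of 0.19, 0.19, 0.27 and 0.21. The lowest r without 1 library was 0.715 in Kasumi-1 at 24 h, 0.646 at 72 h, 0.620 in SKNO-1 at 24 h and 0.725 at 72 h.

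**Figure D3:**
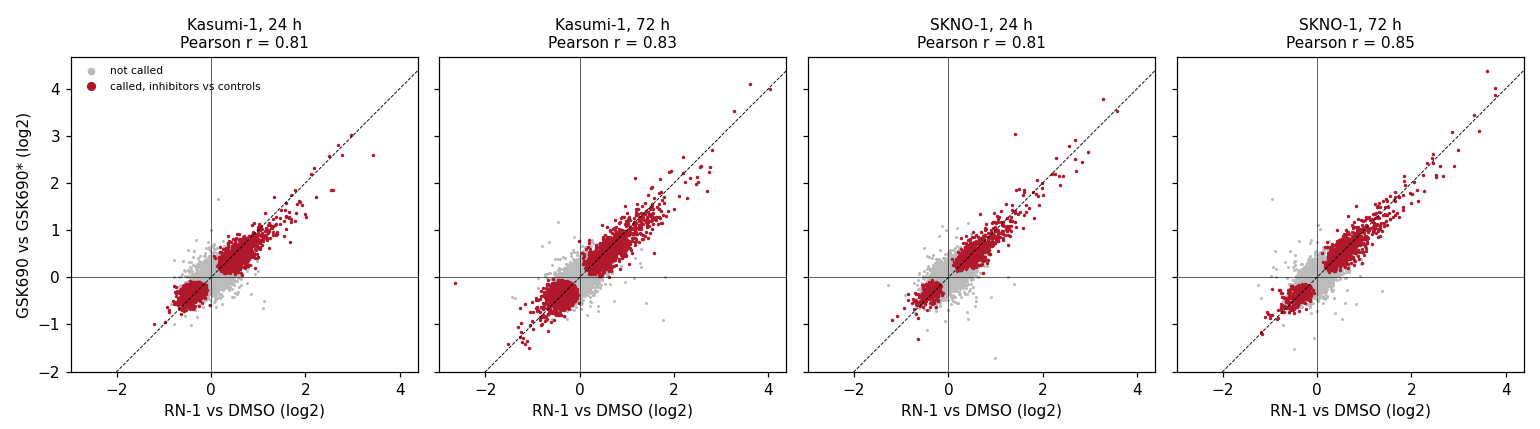
Log2 change with GSK690 against GSK690* (vertical axis) and with RN-1 against DMSO (horizontal axis) for each tested gene, by cell line and time, with genes called in inhibitors against controls in red and a dashed line at equal effects. Pearson r across genes was between 0.810 and 0.852.

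The direct comparison of RN-1 with GSK690 asks whether binding that cannot be reversed adds to the response. LY96 was lower with RN-1 by log2 -0.21 (95% interval -0.63 to 0.22) and -0.35 (-0.77 to 0.07) in Kasumi-1 at 24 and 72 h, which does not pass. PI16 differed by 0.08 (-0.26 to 0.42) and 0.13 (-0.21 to 0.47), KCTD12 by -0.09 (-0.37 to 0.19) and -0.34 (-0.62 to -0.06, adjusted p = 0.676), and GFI1B in SKNO-1 at 72 h by -0.29 (-1.60 to 1.02). By limma, 0 genes passed in Kasumi-1 at 24 h and 0 in SKNO-1 at either time, with 86, 613 and 120 genes at an unadjusted p under 0.05. In Kasumi-1 at 72 h 1 gene passed, with 839 at an unadjusted p under 0.05. It is CD86, with 1.54 ± 0.275 FPKM in 2 RN-1 and 3.62 ± 0.390 FPKM in 2 GSK690 libraries (log2 -0.87, 95% interval -1.14 to -0.59, adjusted p = 0.0196). With no filter 9 and 5 genes passed in Kasumi-1 at 24 and 72 h and 4 and 3 in SKNO-1. In Kasumi-1 at 72 h the count was 0 with a pseudocount of 0.1, with quantile normalization and in the fit on 8 libraries, and 1 with the median of ratios. Without GSK690 replicate 1, GSK690 replicate 2 or RN-1 replicate 1 the count was 0 (CD86 adjusted p = 0.0631 to 0.802), and without RN-1 replicate 2 it was 92. In SKNO-1 at 24 h it was 1 without GSK690 replicate 2. On simulated data, where libraries varied independently, this comparison called 88% to 98% of the genes given an effect of log2 1 in the 4 sets. It called 36% to 60% of those given 0.5.

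GSK690* against DMSO asks whether the isomer leaves expression as the vehicle does. By limma no gene passed in any set, with 305, 111, 218 and 268 genes at an unadjusted p under 0.05 in Kasumi-1 at 24 and 72 h and SKNO-1 at 24 and 72 h. Each of these counts is under 0.05 of the genes tested, the share that chance alone would bring. Without DMSO replicate 1 in Kasumi-1 at 24 h 2 genes passed, and without GSK690* replicate 2 in SKNO-1 at 24 h 2 genes passed. With no filter 8 and 3 genes passed in Kasumi-1 at 24 and 72 h and 1 in SKNO-1 at 72 h, and with a pseudocount of 0.1 1 passed in Kasumi-1 at 72 h. CD86 differed by log2 0.09 (95% interval -0.19 to 0.36) in Kasumi-1 at 24 h, PI16 by 0.10 (-0.25 to 0.44) and KCTD12 by -0.03 (-0.31 to 0.25). LYZ stood at 21.1 FPKM with GSK690* and 9.72 with DMSO (log2 1.01, 0.50 to 1.52), SERPINB8 differed by 0.83 (0.55 to 1.11) and GLIPR1 by 0.78 (0.31 to 1.26), none of which passed the correction.

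The responses at 72 and 24 h were compared by a test of the difference itself. The library names have 1 prefix at 24 h and others at 72 h, so an effect of the library series on the response cannot be told apart from time. In Kasumi-1 PI16 gained log2 1.33 (adjusted p = 4.25e-04), KCTD12 1.11 (4.25e-04), FXYD7, a regulator of the sodium pump, 0.91 (0.00211) and MARCKS, an actin-binding protein, 0.89 (0.00858). In all, 23 genes had a higher and 1 a lower change at 72 h, with 622 at an unadjusted p under 0.05. The count of 24 was 15 without DMSO replicate 2 or 14 without RN-1 replicate 1 of the 24 h set, and 15 without GSK690* replicate 1 of the 72 h set. With a pseudocount of 0.1 PI16 and FXYD7 no longer passed. In SKNO-1 limma found 0 genes, with 153 at an unadjusted p under 0.05.

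The lines were compared in the same way, as Kasumi-1 minus SKNO-1. They differ in some of the most raised genes. PI16 was raised in Kasumi-1 and stood at 0.121 ± 0.132 FPKM or less in SKNO-1, a difference of log2 2.53 ± 0.17 at 24 h and 3.92 at 72 h (adjusted p = 7.06e-09 and 1.09e-12). CLEC4A went the other way, by -3.51 and -3.48 (1.35e-05 and 5.78e-06), as did WFDC1 by -3.03 and -3.48, FCGR2B by -2.77 and -2.81, and GZMA by -1.93 and -1.99. WFDC1 rose in SKNO-1 and fell in Kasumi-1 at 72 h, by 0.85. KCTD12 and LYZ rose in both lines and more in Kasumi-1, by 1.03 and 1.74 at 24 h and by 2.12 and 1.09 at 72 h. CTSS differed by 0.85 and 0.87 and ANXA2 by -1.62 and -1.21. The difference of SERPINB8, 1.17 and 0.80, became -0.10 and -0.74 with a pseudocount of 0.1, where it did not pass, since it stood at 0.153 ± 0.0542 FPKM in SKNO-1 controls. At 24 h 87 genes had a higher and 46 a lower change in Kasumi-1, and at 72 h 275 and 138. The 24 h count of 133 was 86 and 85 without Kasumi-1 GSK690 replicate 1 and 2, 81 without SKNO-1 DMSO replicate 1, 84 without SKNO-1 GSK690 replicate 1 and 87 without SKNO-1 RN-1 replicate 1. The media differ between the lines (20% serum for Kasumi-1, 10% serum with 10 ng/mL GM-CSF for SKNO-1), and line and medium cannot be told apart. At 72 h the treatment time may differ too, as the SKNO-1 protocol gives 4 days, and the library name prefixes differ in part. Neither can be told apart from line there.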

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

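None of the tests in this part was chosen only after its result was seen, though the patterns they weigh were found in the data.

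The response to the inhibitors differed between times in Kasumi-1 and between the lines, by a test of the difference itself. Between 72 and 24 h in Kasumi-1, 24 genes differed, among them PI16 (log2 1.33), KCTD12 (1.11), FXYD7 (0.91), MARCKS (0.89) and SPINK2 (0.74). In a fit on the 16 libraries of the line 42 genes differed, and 4 of 100 regroupings, with the real one included, gave as many. A regrouping also breaks up the response that both times share, so this test cannot decide whether chance gave the difference. The highest of the others gave 5639. A regrouping that mirrors the labels in 1 set would turn the shared response into a difference, but whether this one did so was not tested. In SKNO-1 the real grouping gave 0 genes (highest other 1810), a count that 100 of 100 regroupings reach by construction, so they decide nothing there. SPINK2 was lost in 14 of the 16 fits without 1 library, all but those without Kasumi-1 DMSO replicate 2 at 24 h and RN-1 replicate 2 at 72 h (adjusted p = 0.0545 to 0.128).

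Between the lines, 133 genes differed at 24 h and 413 at 72 h. As Kasumi-1 minus SKNO-1 at 24 h, PI16 differed by log2 2.53, LYZ by 1.74, IL8 by 1.48, SERPINB8 by 1.17, KCTD12 by 1.03, CTSS by 0.85 and HERC5 by 0.75. FCRLA differed by -0.58, ANXA2 by -1.62, FCGR2C by -1.91, GZMA by -1.93, TSPAN7 by -2.10, FCGR2B by -2.77, WFDC1 by -3.03 and CLEC4A by -3.51. At 72 h, PI16 differed by 3.92, KCTD12 by 2.12, FXYD7 by 1.41, KCNH2 by 1.20, LYZ by 1.09, TRIM22 by 0.95, NKG7 and LY96 by 0.91, CTSS by 0.87, STON1 by 0.83, NDRG1 and SERPINB8 by 0.80, SPINK2 by 0.78, SIPA1L2 by 0.75, HERC5 by 0.68, MARCKS by 0.59, CD79B by 0.58, NPC2 by 0.47 and OLFM4 by 0.44. CCL5 differed by -0.82, ANXA2 by -1.21, ASS1 by -1.23, GZMA by -1.99, FCGR2C by -2.11, TSPAN7 by -2.48, FCGR2B by -2.81, WFDC1 and CLEC4A by -3.48 and GFI1B by -3.59. FCGR2B and FCGR2C are near copies, so a read may be assigned to the wrong member. STON1 was lost without SKNO-1 GSK690 or RN-1 replicate 1 at 72 h (adjusted p = 0.0534 to 0.0549) and OLFM4 without Kasumi-1 DMSO or GSK690* replicate 1 at 72 h (0.0516 to 0.0562). FCRLA at 24 h was lost without any 1 of the 16 libraries (0.0609 to 0.125), and in 12 of 16 such fits TRIM22 was lost at 72 h (up to 0.118), NPC2 in 9 (0.103), SIPA1L2 in 7 (0.0700) and MARCKS in 7 (0.0733). SERPINB8 changed sign with a pseudocount of 0.1.

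For the difference between the lines, an exchange of the lines' libraries at 72 h was argued against, since 131 of the 133 genes (98.5%) had the same sign of the difference at 72 h (r = 0.948 across genes). Values near the floor are not the whole cause, as 126 of the 413 genes at 72 h (30.5%) stood at 5 FPKM or more in the controls of both lines. They may have a part, as the mean over the 4 agents was below 1 FPKM for 101 of the 413 in Kasumi-1 and for 144 in SKNO-1. Scaling is argued against too, since 87.9% of the 413 passed again with quantile normalization and 95.9% with the median of ratios. Of the 413, 246 were called in Kasumi-1 alone, 91 in SKNO-1 alone, 61 in both in the same direction and 9 in both in opposite directions. A biological difference between the lines remains a candidate explanation, which the different media leave open. At 72 h, so do the 4 days that the SKNO-1 protocol gives and the library name prefixes, which differ in part between the lines. Of 100 regroupings only the real one gave as many genes at 24 h (192 in a fit on those libraries, highest other 141) and at 72 h (457, highest other 418). A regrouping also breaks up the response that the lines share, so the regroupings cannot decide whether chance gave these counts.

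The calls of inhibitors against controls were weighed against all 35 splits of the 8 libraries of each set into 4 and 4, in fits on those 8, and chance can be excluded in all 4 sets. In Kasumi-1 at 24 h, only the real split, 1 of 35, gave 3822 genes (highest other 9), and at 72 h it gave 2982 (highest other 0). In SKNO-1 it gave 490 at 24 h (highest other 9) and 798 at 72 h (highest other 341). The 341, and both counts of 9, came from the split by replicate number. For the lists, the real split gave 14 in Kasumi-1 at 24 h (highest other 13), 15 at 72 h (14) and 13 in SKNO-1 at 72 h (10), 1 of 35 each. Splits with 0 or 1 called genes reached those 13, 14 and 10 lists. Each of those splits keeps 3 of the 4 inhibitor libraries on 1 side, so it still holds part of the response. They therefore cannot decide whether chance gave the number of lists. Splits with 2 inhibitor libraries on each side gave at most 6 lists in Kasumi-1 at 24 h, 5 at 72 h and 5 in SKNO-1 at 72 h. In SKNO-1 at 24 h such splits gave up to 10. In SKNO-1 at 24 h the real split gave 11, 6 of 35 splits gave as many and the highest other gave 13, so chance cannot be excluded for the number of lists.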

How the results depend on the processing

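The fit without GSK690* among the controls and the means over the 4 sets were added after the data were seen; the other alternatives were planned, and unless stated the cause of a change was not tested. Sets are in the order Kasumi-1 at 24 and 72 h, SKNO-1 at 24 and 72 h.

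With a pseudocount of 0.1, GSK690* against DMSO gave 1 gene in Kasumi-1 at 72 h, RN-1 against GSK690 gave 1 at 24 h and 0 at 72 h in Kasumi-1, and 15 genes differed between times in Kasumi-1. Pearson r was 0.766 in Kasumi-1 at 24 h, 0.736 in SKNO-1 at 24 h and 0.803 at 72 h, where Spearman rho was 0.698. The means over the 4 sets gave 11 genes for GSK690* and 0 for RN-1 against GSK690. SERPINB8 reversed between the lines, to -0.10 at 24 h (adjusted p = 0.945) and -0.74 at 72 h (0.124), because a smaller pseudocount enlarges changes from low values (0.120 FPKM with DMSO in SKNO-1 at 24 h). With no filter, GSK690* gave 8, 3 and 1 genes in Kasumi-1 at 24 and 72 h and SKNO-1 at 72 h, RN-1 against GSK690 gave 9, 5, 4 and 3, time gave 56 in Kasumi-1 and 1 in SKNO-1, and the mean of RN-1 against GSK690 gave 5. Spearman rho was then 0.656, 0.607 and 0.654 in Kasumi-1 at 24 h and SKNO-1 at 24 and 72 h. With quantile normalization RN-1 against GSK690 gave 0 in Kasumi-1 at 72 h.

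In fits on the 8 libraries of a set alone, RN-1 gave 1650, 892, 23 and 116 genes, GSK690 gave 700, 13 and 98 in the last 3 sets, and RN-1 against GSK690 gave 0 in Kasumi-1 at 72 h. Inhibitors against controls gave 160 and 400 in SKNO-1 at 24 and 72 h, and as 2 groups of 4 it gave 3832 in Kasumi-1 at 24 h and 491 and 799 in SKNO-1. These fits take the spread from 1 set alone, with fewer libraries. Fewer libraries alone do not account for the moves, as inhibitors against controls rose from 2479 to 3339 in Kasumi-1 at 24 h in the fit on 8. The median absolute log2 difference between replicates was 0.0960 to 0.121 in Kasumi-1 at 24 h and 0.101 to 0.198 at 72 h. In SKNO-1 it was 0.0847 to 0.173 at 24 h and 0.138 to 0.187 at 72 h. With GSK690* left out of the controls, inhibitors against controls gave 668 in SKNO-1 at 24 h. With a block for replicate number, RN-1 gave 2348, 2548, 1047 and 1066, GSK690 gave 1505, 2466, 636 and 1065, and inhibitors against controls gave 3733, 2306 and 2715 in Kasumi-1 at 24 h and SKNO-1 at 24 and 72 h, with 1198 up and 1108 down and 1382 up and 1333 down in the last 2. GSK690* then gave 3 in Kasumi-1 at 24 h and 35 as a mean over sets, RN-1 against GSK690 gave 3 in Kasumi-1 at 72 h, time gave 129 in Kasumi-1, and line gave 521 and 1007. The labels give same-numbered replicates no shared batch, and between pairs of groups the deviations from the group means of same-numbered libraries correlated with r = 0.0432 to 0.697. With camera's estimated correlation 1, 1, 2 and 3 lists were called. Over the 4 sets, list calls lost and gained were 14 and 16 with fry, 9 and 2 with quantile normalization, 8 and 0 with no filter, 4 and 0 with the median of ratios, 2 and 4 with a pseudocount of 0.1, 2 and 4 in fits on 8 libraries, 1 and 4 with 2 groups of 4, 5 and 2 with GSK690* left out, and 1 and 0 with the prefix term.

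Without 1 library, where a lone replicate is assumed to vary like the other groups, RN-1 gave 273 to 510, 587 to 1687, 87 to 536 and 201 to 482 genes. GSK690 gave 130 to 299, 391 to 593, 63 to 438 and 155 to 426, and inhibitors against controls 1498 to 2095, 2022 to 2852, 387 to 1451 and 860 to 1602. GSK690* gave 0 to 2 at 24 h and 0 at 72 h in both lines. RN-1 against GSK690 gave 0 and 0 to 92 in Kasumi-1 and 0 to 1 and 0 in SKNO-1. Time gave 14 to 30 in Kasumi-1 and 0 in SKNO-1, and line 81 to 187 and 313 to 483. Lists were 10 to 14, 11 to 13, 11 to 14 and 10 to 13. Pearson r was 0.715 to 0.810, 0.646 to 0.883, 0.620 to 0.786 and 0.725 to 0.791, and Spearman rho 0.638 to 0.765, 0.496 to 0.832, 0.470 to 0.687 and 0.577 to 0.656. The means over the 4 sets gave 2 to 10 and 2 to 3.

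Of 309 called results of single genes, 208 held in each fit without 1 library and 101 were lost in at least 1. Of the results of single genes, 325 of 325 kept their side of the threshold with the replicate block, 317 with the median of ratios, 296 with quantile normalization, 292 with a pseudocount of 0.1 and 291 with no filter. With GSK690* left out 231 of 274 did, with 2 groups of 4 230 of 274, and with 8 libraries alone 196 of 275. With a term for the library name prefix, 66 of 66 did. The unknown depth limits what genes under 1 FPKM can show.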

Other observations

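The means over the 4 sets, the test for inhibitor cells or RNA in the GSK690* libraries and the test of the span of all genes were chosen only after the result was seen, and the bounds of the other tests were written before their values were seen, for patterns found in the data.

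Mean contrasts over the 4 sets set 8 libraries against 8. For GSK690* against DMSO, 7 genes passed, all higher with GSK690*: the tetraspanin CD53 (log2 0.45, adjusted p = 0.00848), CTSS (0.32), TMEM243 (0.42), EVI2B (0.30), SERPINB8 (0.39), GLIPR1 (0.66) and LYZ (0.69, adjusted p = 0.0242). Each of the 7 was also raised by the inhibitors, CD53 by 0.82 to 1.11 in the 4 sets and LYZ by 1.27 to 3.01. CD53 and CTSS passed in all 16 fits without 1 library, TMEM243 in 15, EVI2B in 8, SERPINB8 in 7, GLIPR1 in 6 and LYZ in 5. The count was 2 without SKNO-1 DMSO replicate 1 at 24 h. It was 3 without Kasumi-1 DMSO replicate 2 at 24 h, Kasumi-1 GSK690* replicate 1 at 24 or 72 h, SKNO-1 GSK690* replicate 1 at 24 h, SKNO-1 DMSO replicate 1 at 72 h or SKNO-1 GSK690* replicate 2 at 72 h, and 4 without Kasumi-1 DMSO replicate 2 at 72 h. Of 100 regroupings only the real one gave as many (7, highest other 1). The mean over the 4 sets was chosen after the result was seen, so this test alone cannot exclude chance.

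For RN-1 against GSK690, the mean over the 4 sets gave 2 genes, both lower with RN-1. CD86 differed by log2 -0.47 (95% interval -0.60 to -0.33, adjusted p = 0.00698), with both RN-1 libraries below both GSK690 libraries in all 4 sets. FCRLA, a gene of B cells, differed by -0.47 (adjusted p = 0.00866), with that order in 3 of 4 sets. Both passed in all 16 fits without 1 library, and 240 genes had an unadjusted p under 0.05. With a pseudocount of 0.1 neither gene passed and the count was 0, while it was 2 with quantile normalization or the median of ratios and 5 with no filter. As many genes as the 2 came in 21 of 100 regroupings (highest other 26), so chance cannot be excluded for the count. The median 95% interval of a gene reached 0.142 to either side.

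The lists were also tested for a difference between times and lines. In Kasumi-1 the fall of proliferation genes was weaker at 72 than at 24 h by a median log2 of 0.17 (camera adjusted p = 2.37e-09, and adjusted p = 0.747 with an estimated correlation). In SKNO-1 it was also weaker at 72 than at 24 h, by 0.07 (camera adjusted p = 4.02e-04, estimated 0.978). The fall was deeper in Kasumi-1 than in SKNO-1 at 24 h by -0.31 (camera adjusted p = 5.73e-15, estimated 0.430) and at 72 h by -0.18 (1.15e-05, estimated 0.827). Monocyte and macrophage genes rose more in Kasumi-1 than in SKNO-1, by 0.44 at 24 h (4.49e-04, estimated 0.231) and 0.31 at 72 h (0.0257, estimated 0.685), and class I genes did so at 72 h, by 0.37 (0.00302, estimated 0.769). Mast cell, basophil and eosinophil genes differed at 72 h by -0.40, with the larger rise in SKNO-1 (0.0440, estimated 0.630). None of these differences held with an estimated correlation.

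GSK690* libraries lay between DMSO and the inhibitors on genes raised at least 2-fold by the inhibitors at the other time of the same line. The median log2 of GSK690* over DMSO was 0.19 and 0.19 in Kasumi-1 at 24 and 72 h (173 and 77 genes) and 0.27 and 0.21 in SKNO-1 (122 and 86 genes), where 95% of random lists had medians between -0.03 and 0.04, and a rotation test (fry) passed an unadjusted 0.05 in Kasumi-1 and not in SKNO-1. Scaling is argued against by a lowest median of 0.17 under the other scalings. For replicates 1 and 2 the medians were 0.18 and 0.19 at 24 h and 0.15 and 0.24 at 72 h in Kasumi-1. In SKNO-1 they were 0.39 and 0.14 at 24 h and 0.27 and 0.15 at 72 h. Medians above 0 in 8 of 8 pairs argue against a batch in some GSK690* libraries, but not against a batch shared by all GSK690* libraries. Inhibitor cells or RNA in these libraries would give all genes 1 share of the effect of their source, but genes with a larger share at 24 h also had one at 72 h (Spearman rho at least 0.444 in either line with RN-1, GSK690 or both as the source, shuffled genes up to 0.232). Weak activity of the isomer, or a trace of active compound, may account for the pattern, as the medians of genes that fell were also below 0 in 4 of 4 sets (-0.10, -0.09, -0.17 and -0.11), though fry passed in no set for these.

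In SKNO-1 at 24 h, 105 of the 122 genes raised at least 2-fold at 72 h changed more in replicate 1 than in replicate 2 (medians 1.37 and 0.96). GFI1B stood at 17.0 and 1.53 FPKM in RN-1 replicates 1 and 2. Control cells or RNA in replicate 2 would give all genes 1 share of the effect of replicate 1. Each gene's share had a rho of 0.802 between the compounds, where shuffled genes reached 0.179. But same-numbered libraries of this set deviated together across genes (r = 0.294 to 0.525). That raises rho with or without control cells or RNA, so the test cannot decide whether they had a part. A smaller span of all genes is argued against by the spread across genes. In replicate 2 it was at least 0.987 times that in replicate 1 for each agent, where the effect was 0.702 times as large. The excess in replicate 1 correlated across genes with the change from 24 to 72 h (r = 0.377), as it would if replicate 1 were further along the time course. The 24 h value in that change is the mean of the same 2 replicates, so any cause of a weaker replicate 2 could raise this r. With 0 genes differing between times in SKNO-1, the test cannot point to time. A difference between the cultures before treatment was not tested.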
